A study of Mus musculus with 6 samples.

How the data were processed

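Messenger RNA was measured by RNA sequencing in 6 mouse libraries. They were 3 of androgenetic haploid embryonic stem cells (AG-haESCs), 1 of cells labelled round sperm and 2 of embryonic stem cells labelled XX and cultured with 2i, a pair of inhibitors of MEK and GSK3. Per the labels' protocols, polyA RNA was extracted with a column kit and made into libraries with a stranded mRNA kit from KAPA. AG-haESC cells were collected by flow sorting of haploid cells in G0/G1 after culture on feeder cells in serum replacement medium with 2i. The ESC XX cells grew in serum, LIF and 2i and were collected after a step to remove feeders, with no sort named. The label of the round sperm library carries the same text on sorting and culture as those of the AG-haESCs. Reads were aligned with TopHat2 2.0.13 and expression was estimated with Cuffdiff 2.2.1 against mm9, per the submitters' processing notes. The settings of these tools, including the normalization between libraries and the use of strand, are not given in the sources used here.

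The deposited values were read as FPKM, fragments scaled to the length of the transcript and to the depth of the library. The tables of the ESC XX libraries name the unit. The header of the table that holds the 3 AG-haESC and the round sperm libraries does not, and there the unit was taken from the tool named in the processing notes and from the size of the values. Every table listed the same 23889 gene symbols. The 2 ESC XX libraries came in tables of their own, so they were scaled apart from the other 4. Chromosomes and transcript lengths were looked up by symbol in a GRCm38 annotation, which is another build than mm9. A chromosome was found for 99.5% of the symbols and a length for 94.6%. No coordinates are given because the builds differ.

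The files hold no read counts. Because low FPKM values step by whole fragments, the steps of 2963 genes with 1 annotated transcript were used to estimate depth, which came to about 8.38 M (mega) fragments for A129-2, 17.8 M for AOS-14, 9.63 M for AOS-16, 9.89 M for round sperm, and 15.2 M and 17.3 M for the ESC XX libraries. These depths are approximate and fragments were not recovered gene by gene. In the same estimate, the ESC XX pair differed by little more than counting noise, with a median chi-square of 1.10 times the value expected by chance for genes of 10 to 100 fragments and 1.34 times for 100 to 1000 fragments. The AG-haESC pairs stood at 5.64 to 11.5 times and 17.4 to 44.0 times. The ESC XX libraries were kept as 2 because they exceeded counting noise at the higher counts, but nothing in the labels says that they are separate cultures, and their spread may be technical. The 3 AG-haESC libraries are 3 cell lines with 1 library each, A129-2, AOS-14 and AOS-16 (replicates 1, 2 and 3).

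AG-haESCs were compared with round sperm within their shared table by limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1). Genes reaching an FPKM of at least 1 in at least 1 of the 4 libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, two-sided. With 1 round sperm library the spread comes from the AG-haESC libraries alone, on 2 residual degrees of freedom, and the lone library is assumed to vary like them. The p-values thus measure the spread between these cell lines. Gene lists were tested with camera at a preset correlation of 0.01, with camera's estimated correlation and with fry, adjusted over the 29 lists. Camera sets the genes of a list against the other genes, whereas fry asks only whether the genes of a list changed. With an estimated correlation, camera takes p from the 2 residual degrees of freedom, which limits how small its p can be.

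AG-haESCs and ESC XX were compared by size and overlap and no test was run between them. Tests were kept within a table, as the tables were normalized separately, although a fit on a common scale could have been made. Each of these 5 libraries was rescaled to the same total as TPM, and the median difference of log2(TPM + 1) over the genes kept was removed. This group median was also the one taken from each single line. The list medians of single lines, and their SD, therefore keep any offset of a line's library. A gene was called higher or lower when the group means differed by at least 1 on the log2 scale and all AG-haESC libraries lay on the same side of both ESC XX libraries. Each list's median difference was placed among 10000 random lists of the same size matched on mean expression, which describes these libraries and is no test. All differences are on the log2(value + 1) scale, which understates the change of low genes.

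The methods were tested on simulated data with known changes. Every library was drawn around the AG-haESC means with the spread of the 3 lines, and only genes with a mean of at least 20 FPKM were changed. The 2 libraries standing for ESC XX were near copies of 1 draw, without a difference in scale between tables. Far fewer genes were changed than were called in the real data, which bears on the adjusted p of limma. For these reasons the shares below do not carry over to the real comparisons. For 3 libraries against 1, limma recovered 20 of 100 genes changed by a log2 of 2 and 68 of 100 changed by a log2 of 4, and called 3 of 12360 unchanged genes. For 3 libraries against 2, the size rule recovered 98 of 100 genes at either size and called 714 of 12393 unchanged genes. These 714 were 5.67% of all 12593 genes tested.

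Genes named in the text follow a rule set before the data were examined, as were the lists and the alternatives not described as added. Per comparison these are the 5 called genes with the highest and the 5 with the lowest difference among those with a mean of at least 10 in the higher group, the 2 members of each list with the largest difference (up to 4 where a list leads a paragraph), and Pou5f1, Nanog, Sox2, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1, Xist, H19, Igf2r, Igf2, Prm1 and Tnp1. Gene families and single genes named only in the closing observations were chosen after their values were seen. Alternatives were a pseudocount of 0.1, other filters on low values, other scalings between libraries, other thresholds, no variance trend, and leaving out each replicate. Further alternatives, added after the data were seen, left out genes under 200 nt, X-chromosomal genes or genes listed at 0 throughout a group, or averaged the ESC XX libraries. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.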

Results

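Gene expression was profiled in AG-haESCs, which are embryonic stem cells derived from embryos whose only genome came from a sperm head injected into an enucleated oocyte, to compare them with round sperm and with ESC XX cultured in 2i. The AG-haESC group held 3 libraries, each from its own line (A129-2, AOS-14 and AOS-16), round sperm had 1 library and ESC XX had 2. Estimated depth ran from 8.38 M (mega) fragments in A129-2 to 17.8 M in AOS-14, and between 11406 and 12515 genes reached an FPKM of 1 in each library. Eef1a1, a translation elongation factor, and Rn45s, the ribosomal RNA precursor, were listed at 0 in all 3 AG-haESC libraries. Eef1a1 stood at 6397 and 6462 FPKM in ESC XX, so a value of 0 in these tables can be a failed estimate.

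The 3 AG-haESC lines shared high levels of the pluripotency factors Pou5f1 (1096 ± 268 FPKM, mean ± SD, n = 3), Nanog (359.9 ± 61.6 FPKM) and Sox2 (111 ± 5.84 FPKM), and differed on chromosome 8. Genes of chromosome 8 were higher in A129-2 than in the AOS lines, with a median log2 difference of 0.92 over 478 genes with a mean of at least 10 TPM, relative to the other autosomes. Medians of the other autosomes lay between -0.11 and 0.08. Of the chromosome 8 genes, 93.5% were higher in A129-2 than in the mean of the AOS lines. This share was taken in TPM and not relative to the other autosomes. A lower filter, an FPKM of at least 1 in at least 1 line, kept 12637 genes of all chromosomes. Of these, 633 were in A129-2 at least 2-fold above the mean of the AOS lines and above both. Chromosome 8 supplied 213 of the 633, or 33.6%, against 5.44% of the genes compared. The chromosome, and the genes Zfp42, Meg3 and Rian in the account of the lines, were singled out after their values were seen. Zfp42, a marker of the naive state that lies on chromosome 8, stood at 649 TPM in A129-2, 77.6 in AOS-14 and 72.8 in AOS-16. Imprinted RNAs also varied by line. Meg3 was at 82.4 FPKM in A129-2 against 13.6 in AOS-14 and 15.3 in AOS-16, and Rian, from the same maternally expressed cluster, was at 56.5, 9.64 and 10.6 FPKM. H19, a maternally expressed RNA, was at 4.61 FPKM in A129-2, 44.6 in AOS-14 and 13.9 in AOS-16. Across 12637 genes, which are not independent replicates, Pearson's r was 0.940 between A129-2 and AOS-16 (Spearman's rho 0.929), 0.855 between A129-2 and AOS-14 (0.868) and 0.881 between AOS-14 and AOS-16 (0.902). Genes under 200 nt held 12.7% of the FPKM total in AOS-14, 0.111% in A129-2 and 0.00983% in AOS-16, and with these genes left out, at the same total, r was 0.940, 0.932 and 0.960. The number of genes differing at least 2-fold was 1531, 1778 and 824 in the order first given, 2123, 2346 and 1089 with short genes left out at the same total, and 2499, 2743 and 1519 with a pseudocount of 0.1. Between A129-2 and AOS-14, 715 of these were higher in A129-2 and 1063 in AOS-14, and this balance turned with short genes left out at the same total (1513 and 833) and with quantile normalization (954 and 839). Between AOS-14 and AOS-16 it went from 562 and 262 to 452 and 637 with short genes left out at the same total. Leaving out short genes was not run apart from the rescaling, so these turns cannot be put down to short genes alone. With 1 library per line, differences between lines had no replicate check.

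**Figure D1:**
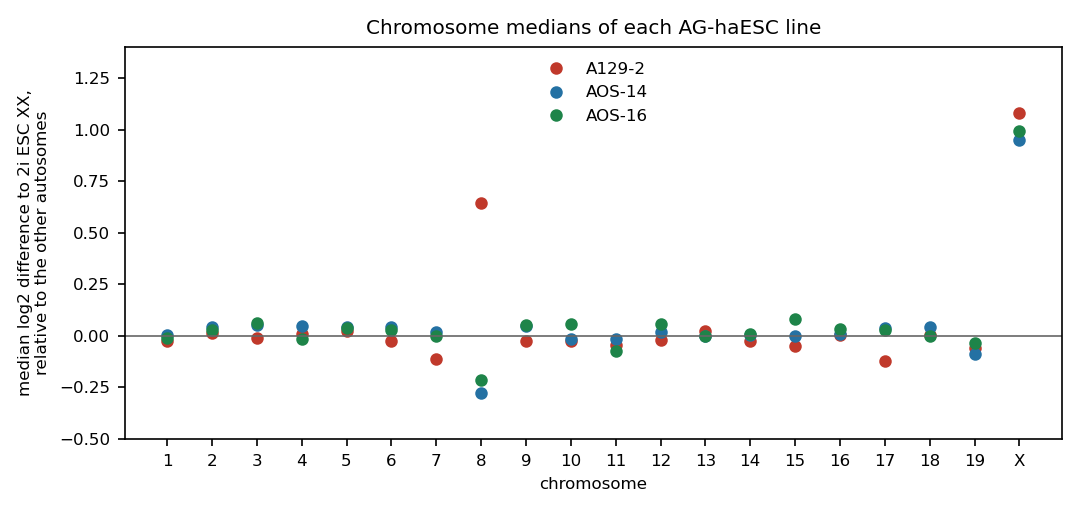
Median log2 difference of each AG-haESC line to the mean of the 2 ESC XX libraries, per chromosome, for genes with a mean of at least 10 TPM and relative to the other autosomes; points are the 3 lines. On chromosome 8, A129-2 lies at 0.64 and AOS-14 and AOS-16 at -0.28 and -0.21, and on the X chromosome all 3 lie between 0.95 and 1.08.

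Against round sperm, AG-haESCs expressed the pluripotency network, and transcripts of spermatids, the haploid cells that form sperm, fell to low levels. Of 25 pluripotency genes 20 rose and none fell, and the list's median log2 difference was 4.67, which is 5.16 above the median of all genes (limma camera, adjusted p = 1.40e-07; adjusted p = 0.457 with an estimated correlation). Pou5f1, the factor also called Oct4, rose by 7.11 ± 0.38 (log2 ± SE, limma, n = 3 and 1, adjusted p = 0.00234), Nanog by 7.59 ± 0.27 (adjusted p = 0.00102), and Sox2 by 6.59 ± 0.11 (adjusted p = 0.000205). Dppa5a, an RNA-binding protein of pluripotent cells, rose by 8.16 ± 0.32 (adjusted p = 0.00124) and Tdgf1, a NODAL co-receptor, by 7.42 ± 0.25 (adjusted p = 0.000924). All 28 measured spermatid genes fell, with a median of -9.49, or -9.00 relative to all genes (adjusted p = 3.89e-08; adjusted p = 0.457 with an estimated correlation). The protamines Prm1 and Prm2 and the transition proteins Tnp1 and Tnp2, which replace histones as sperm chromatin condenses, stood at 10837, 6997, 9442 and 8030 FPKM in round sperm. In AG-haESCs all 4, and Meig1, which is needed for spermiogenesis, were listed at 0 in A129-2 and AOS-16, and in AOS-14 they lay between 0.227 and 0.772 FPKM, against 6341 FPKM of Meig1 in round sperm.

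X-linked and Y-linked genes moved in opposite directions. Of 26 X-linked genes 22 rose and none fell (median 2.92, adjusted p = 2.14e-08; adjusted p = 0.457 with an estimated correlation), while all 5 measured Y-linked genes fell (median -2.39, adjusted p = 0.00486; adjusted p = 0.457 with an estimated correlation). Pdha1, a subunit of pyruvate dehydrogenase, rose by 7.28 ± 0.27 (adjusted p = 0.00115), and Pgk1, a glycolytic enzyme, by 7.22 ± 0.52 (adjusted p = 0.00405). Rps4x, a ribosomal protein, and Bex1, both X-linked, were among the 5 genes with the highest difference, at 9.02 and 8.76, beside Ftl1, the ferritin light chain, at 9.01, Igfbp2, which binds insulin-like growth factors, at 8.67 and Slc2a1, a glucose transporter, at 8.36. Eif2s3y, a Y-linked translation initiation factor, had 79.4 FPKM in round sperm and at most 0.0969 in an AG-haESC library. Zfy1, a Y-linked zinc finger gene, had 4.40 FPKM in round sperm and was listed at 0 in all 3 lines. Xist, the RNA that coats an inactive X, was at 1.02 ± 0.226 FPKM in AG-haESCs and 0.0362 in round sperm and was not called (0.96 ± 0.16, adjusted p = 0.0208), as its difference lay under 1. It was called with a pseudocount of 0.1 (adjusted p = 0.00694), after rescaling to the same total (adjusted p = 0.0453), also with short genes left out (adjusted p = 0.0296), and after quantile normalization (adjusted p = 0.0359). No other measured X inactivation RNA was called. X inactivation RNAs passed the test as a list in neither direction (adjusted p = 0.252).

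Genes of DNA replication and of DNA methylation rose. Of 14 G1-S and S phase genes 10 rose (median 2.97, adjusted p = 0.000607; adjusted p = 0.457 with an estimated correlation), led by the replication licensing factors Mcm2 (6.77 ± 0.19, adjusted p = 0.000653) and Mcm3 (6.52 ± 0.23, adjusted p = 0.00100). Of 12 genes of the DNA methylation machinery 9 rose and none fell (median 1.95, adjusted p = 0.000852; adjusted p = 0.502 with an estimated correlation). The dioxygenases Tet1 and Tet2, which oxidise methylated cytosine, rose by 4.41 ± 0.21 (adjusted p = 0.00194) and 4.18 ± 0.22 (adjusted p = 0.00224), the maintenance methyltransferase Dnmt1 by 3.80 ± 0.34 (adjusted p = 0.00606), and the de novo methyltransferases Dnmt3a and Dnmt3b by 1.94 ± 0.16 (adjusted p = 0.00524) and 3.85 ± 0.37 (adjusted p = 0.00697). Dnmt3l, their cofactor, rose by 1.95 ± 0.41 (adjusted p = 0.0351) but lost its call without A129-2 (adjusted p = 0.0679) or without AOS-14 (adjusted p = 0.121). Uhrf1, which brings Dnmt1 to replicated DNA, was at 112 ± 34.5 FPKM in AG-haESCs and 62.4 in round sperm and was not called (0.79 ± 0.47, adjusted p = 0.238). It was called after rescaling to the same total (adjusted p = 0.0213), also with short genes left out (adjusted p = 0.0278), and after quantile normalization (adjusted p = 0.0167). Of 13 p53 targets 11 rose (adjusted p = 0.000852; adjusted p = 0.547 with an estimated correlation), among them the cell death effector Bax (6.59 ± 0.24, adjusted p = 0.00111) and Phlda3 (5.30 ± 0.33, adjusted p = 0.00314). Of 14 glycolysis genes 8 rose (adjusted p = 0.00497; adjusted p = 0.598 with an estimated correlation). Of 16 genes of cholesterol and fatty acid synthesis 9 rose and 3 fell (adjusted p = 0.00839; adjusted p = 0.547 with an estimated correlation), with the desaturase Scd2 up by 5.82. Of 13 ERK pathway targets 8 rose and 1 fell (adjusted p = 0.00417; adjusted p = 0.547 with an estimated correlation), and of 16 stress and immediate early genes 7 rose and 1 fell (adjusted p = 0.0177; adjusted p = 0.547 with an estimated correlation). Of 16 feeder fibroblast genes 4 rose and none fell (adjusted p = 0.0107; adjusted p = 0.598 with an estimated correlation), and of 11 post-implantation epiblast genes 5 rose and 1 fell (adjusted p = 0.0349; adjusted p = 0.547 with an estimated correlation). Of 10 housekeeping genes 7 rose and 1 fell (adjusted p = 0.00841; adjusted p = 0.457 with an estimated correlation). The housekeeping median was 1.76, against 1.95 for DNA methylation, 1.79 for immediate early, 1.70 for fibroblast and 1.49 for epiblast genes. Rises of this size were thus not particular to those lists. Medians were higher for ERK targets (2.07), cholesterol and fatty acid synthesis (2.52), glycolysis (3.52) and p53 targets (3.78). The share of fibroblast genes that rose was near that of all genes tested (3632 of 15938), and fry did not call this list. Ctgf and Fn1 led the fibroblast list (5.50 and 5.46), and Fos and Ier2 the immediate early list (5.00 and 5.25). Both of the latter lost their call without AOS-14 (Fos adjusted p = 0.0777, Ier2 adjusted p = 0.109) or without AOS-16 (adjusted p = 0.0789 and adjusted p = 0.0869). The housekeeping gene that fell was Tbp, the TATA-binding protein (-3.18 ± 0.09, adjusted p = 0.000637), named outside the rule after its value was seen. The epiblast call was absent after rescaling to the same total (adjusted p = 0.147) or quantile normalization (adjusted p = 0.134), and that of the immediate early list after quantile normalization (adjusted p = 0.0533).

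Imprinted genes are expressed from the allele of a single parent, and those expressed from the paternal allele rose as a list. The housekeeping list also rose (median 1.76), and whether the rise here was particular to imprinted genes was not tested. Of 20 measured paternally expressed genes 12 rose and 3 fell (median 2.17, adjusted p = 0.00103; adjusted p = 0.457 with an estimated correlation), with the amino acid transporter Slc38a4 up by 6.36 ± 0.63 (adjusted p = 0.00749) and Impact by 5.23 ± 0.76 (adjusted p = 0.0165). Slc38a4 lost its call without AOS-14 (adjusted p = 0.0530), and Impact without AOS-14 (adjusted p = 0.0789) or without AOS-16 (adjusted p = 0.0501). Of 17 maternally expressed genes 3 rose and 6 fell, and the list passed the test in neither direction (adjusted p = 0.459). Igf2r, a receptor that clears IGF2, rose by 3.92 ± 0.11 (adjusted p = 0.000615), and Asb4 and Slc22a18 fell (Asb4 -5.65 ± 0.09, adjusted p = 0.000175, Slc22a18 -4.66 ± 0.12, adjusted p = 0.000527). Igf2, a growth factor, was at 3.13 ± 1.84 FPKM in AG-haESCs and 1.52 in round sperm and was not called (adjusted p = 0.550), but was without A129-2 (adjusted p = 0.0344). H19, which varied between the lines, was not called (adjusted p = 0.264). Of 21 germline genes 4 rose and 10 fell (adjusted p = 0.576), and of 12 meiotic spermatocyte genes 8 fell and none rose (adjusted p = 0.0508). The spermatocyte list passed the test in 6 of 11 alternatives, with an adjusted p from 0.0250 without A129-2 to 0.502 with an estimated correlation. It was 0.0850 without AOS-14, 0.0411 without AOS-16 and 0.0408 after rescaling to the same total. Mael, a piRNA pathway gene, went from 2530 FPKM in round sperm to 11.3 ± 4.29 in AG-haESCs (-7.75 ± 0.53, adjusted p = 0.00373), and Hspa2, a testis heat shock protein, fell by 8.32 ± 0.14 (adjusted p = 0.000216). Among spermatogonial genes 5 rose and 2 fell of 9 (adjusted p = 0.312), including the transcription factor Sohlh2 (3.93 ± 0.19, adjusted p = 0.00186) and Stra8, a retinoic acid target (4.23 ± 0.78, adjusted p = 0.0264). The Stra8 call was lost without A129-2 (adjusted p = 0.0736) or without AOS-16 (adjusted p = 0.0989). The remaining lists did not pass the test, apart from WNT targets and 2-cell-stage with no filter on low values. They were G2-M phase (2 rose and 6 fell of 20, adjusted p = 0.979), WNT targets (4 and 1 of 6, 0.170), and trophoblast (3 and 1 of 10, 0.103, and 0.0374 without AOS-14). The others were primitive endoderm (4 and 2 of 11, 0.308), mesoderm and neural (1 and 2 of 8, 0.963), 2-cell-stage (1 and 1 of 8, 0.158, and 0.0476 without AOS-16), Sertoli (1 and 1 of 5, 0.921), Leydig (0 and 0 of 3, 0.668) and haematopoietic (0 and 1 of 3, 0.565).

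Over all 15938 genes tested, limma called 9864, of which 3632 were higher and 6232 lower in AG-haESCs. With p adjusted over the list alone, 21 of the 29 lists gave the same counts of genes that rose and fell. Adjusted over the list alone, the stress and immediate early list fell to 1 and 0, trophoblast to 1 and 1, primitive endoderm to 3 and 2, mesoderm and neural to 0 and 2, G2-M phase to 1 and 5, and the maternally expressed imprinted list to 3 and 5. The X-linked list went to 23 and 0, and cholesterol and fatty acid synthesis to 10 and 4. The median of all genes was -0.49 on the log2 scale as deposited, and 36.8% of calls were higher in AG-haESCs. Rescaled to the same total the median was 0.49 and 52.2% of 9320 calls were higher, and after quantile normalization it was 0.42 and 50.9% of 9376. The balance of directions and the size of each log2 difference thus depended on the scaling, which moved the median of all genes from -0.49 to 0.49, while all 120 named genes kept their sign when called. With an estimated correlation no list passed camera (1 did at an unadjusted p under 0.05) and fry called 22 of 29. The round sperm library had no replicate.

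**Figure D2:**
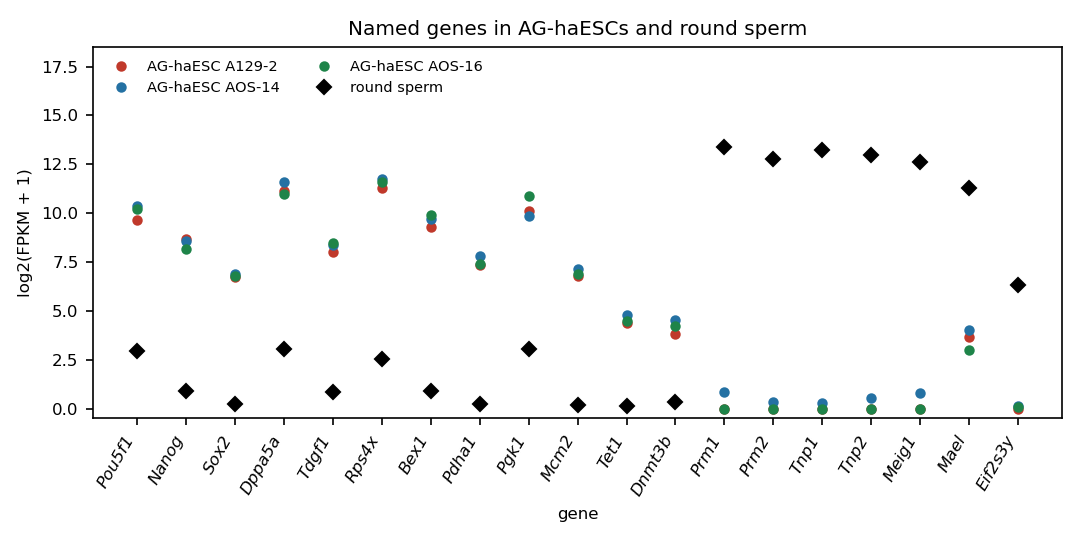
Expression of 19 named genes as log2(FPKM + 1) in the 3 AG-haESC lines (circles) and the round sperm library (diamonds). Pluripotency, X-linked, replication and DNA methylation genes lie higher in all 3 lines, and Prm1, Prm2, Tnp1, Tnp2, Meig1, Mael and Eif2s3y lie higher in round sperm.

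The comparison with ESC XX asked how the haploid lines differ from embryonic stem cells that are labelled XX and grown in 2i. Most pluripotency genes stayed within the bounds of the rule, whereas X-chromosomal and germline genes were higher in AG-haESCs and 2-cell-stage, fibroblast, ERK, WNT and G2-M genes were lower. Of 25 pluripotency genes 22 met neither bound, and the list's median difference was -0.16 ± 0.15 (log2, SD of the 3 lines' medians), at percentile 5.61 of random lists. Without AOS-14 the median was -0.27 and the list lay below the central 95% of random lists (percentile 0.885), and without A129-2 the median was 0.05 (percentile 57.1). Pou5f1 was at 1859 ± 294 TPM in AG-haESCs (mean ± SD, n = 3) and at 1268 and 1240 TPM in the 2 ESC XX libraries, Nanog at 623 ± 151 against 791 and 792, and Sox2 at 191 ± 22.6 against 289.7 and 272. Tbx3, a naive-state transcription factor, was lower in AG-haESCs, with a difference of -1.34 ± 0.36 (log2 ± SD of the AG-haESC libraries, n = 3), as was Nr5a2, an orphan nuclear receptor (-1.06 ± 0.55). Dppa3, a protein of oocytes and naive cells, was higher (1.09 ± 0.73). The Dppa3 call was absent when the median difference was kept, and that of Nr5a2 was absent with FPKM as deposited.

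X-chromosomal genes were higher in AG-haESCs across the chromosome. Over 314 X-chromosomal genes with a mean of at least 10 TPM the median difference was 0.95 (quartiles 0.59 and 1.47), and 91.7% of them were higher, against autosome medians from -0.09 to 0.02. Relative to the autosomes the X stood at 1.08 in A129-2, 0.95 in AOS-14 and 0.99 in AOS-16. The median X-chromosomal gene was at 1.21 to 1.35 times the median autosomal gene in these lines against 0.605 and 0.623 times in ESC XX. X-chromosomal genes were 233 of the 806 genes called higher (28.9%) and 3.98% of the genes kept. This whole-chromosome set was chosen after its values were seen. In the list of 26 X-linked genes set beforehand, 21 were higher and 6 met the bound, with a median of 0.64 ± 0.21, above all 10000 random lists. Dusp9, a phosphatase of the ERK pathway, was at 221 ± 57.7 TPM against 24.2 and 24.5, and Pgk1 at 2299 ± 1050 against 755 and 761 (1.60 ± 0.69). All 5 genes with the highest differences lie on the X chromosome, namely Gm364 (6.03 ± 1.02), Efhc2 (5.28 ± 0.80), the lymphocyte-regulated family members Xlr5b (4.61 ± 1.09) and Xlr5a (4.53 ± 1.34), and 4930550L24Rik (4.53 ± 0.93). Xlr5a and Xlr5b are near-identical copies whose reads may have been split between them, so their separate values are uncertain. Xist was lower in AG-haESCs, at 1.80 ± 0.656 TPM against 11.5 and 11.9 (-2.10 ± 0.33), and was the only 1 of 3 measured X inactivation RNAs that met the bound (Ftx 0.35 ± 0.27).

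Germline genes, which DNA methylation silences in somatic cells, were higher in AG-haESCs. Of 21 measured 16 met the bound and all 21 were positive, with a median of 1.79 ± 0.75, above all 10000 random lists. Taf7l, an X-linked germ cell TATA-binding protein partner, was at 127, 31.9 and 39.6 TPM in A129-2, AOS-14 and AOS-16 against 1.97 and 1.78 (4.38 ± 1.06), and the reproductive homeobox genes Rhox2a, Rhox9 and Rhox6 were higher by 3.86 ± 1.32, 3.64 ± 0.78 and 3.47 ± 0.62. The Rhox genes have near-identical copies, so values of single members are uncertain. These 4 lie on the X chromosome. Among the 17 autosomal members 12 met the bound, with a median of 1.61. Meiotic spermatocyte genes included 5 higher of 11 (median 0.97 ± 0.23, percentile 99.98), led by the synaptonemal complex genes Sycp1 (2.35 ± 0.57) and Sycp3 (1.79 ± 1.18), which the germline list also holds. Among 8 spermatogonial genes 2 were higher and 3 lower, with Sohlh2 at 81.0 ± 19.3 TPM against 8.64 and 8.83 and Stra8 at 38.2 ± 22.0 against 4.03 and 2.45. Of the DNA methylation machinery 1 gene of 12 met the bound, Dnmt3l, at 274 ± 99.9 TPM against 112 and 116. Dnmt1 differed by -0.32 ± 0.20, Dnmt3a by 0.21 ± 0.37, Dnmt3b by -0.72 ± 0.17, Uhrf1 by -0.36 ± 0.29 and Zfp57, a protector of imprints, by -0.91 ± 0.03, and none of these 5 met the bound. The list lay below the central 95% of random lists (percentile 1.72), but not without A129-2 (7.49).

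Genes of the 2-cell-stage program were lower in AG-haESCs. All 13 measured met the bound, with a median of -2.95 ± 0.35, below all 10000 random lists. The zinc finger genes Zscan4e and Zscan4f were at 0.657 ± 0.229 and 4.17 ± 2.47 TPM in AG-haESCs against 55.7 and 49.4 and 138 and 163 in ESC XX, although Zscan4 copies share reads and the share of each is uncertain. ERK targets and WNT targets were also lower, in a comparison where fibroblast genes were lower as well (14 of 16, median -3.28). Of 13 ERK targets 8 were lower (median -1.15 ± 0.20), among them Egr1, an immediate early transcription factor, at 3.16 ± 1.37 TPM against 395 and 380.4, and Myc at 1.16 ± 0.892 against 30.4 and 28.6. Of 10 WNT targets 6 were lower (median -1.23 ± 0.26), among them the homeobox gene Cdx1 (-3.98 ± 0.15) and Sp5 (-3.41 ± 0.17), and of 16 stress and immediate early genes 5 were lower, with Fosb at -2.23 ± 0.68. The media differed in serum and serum replacement, and the lists of ERK targets and immediate early genes share Egr1. Of 20 G2-M genes 10 were lower (median -0.99 ± 0.23), including the mitotic kinase Aurka (-1.67 ± 0.19) and Ube2c (-1.54 ± 0.24), whereas 0 of 14 G1-S and S phase genes met the bound, where Tyms (-0.60 ± 0.33) and Pcna (-0.46 ± 0.08) differed most. The protocol of the AG-haESCs names a sort for cells in G0/G1, and that of ESC XX names none.

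Fibroblast genes, fixed beforehand as markers of feeder cells, were lower in AG-haESCs. Of 16 genes 14 met the bound, with a median of -3.28 ± 1.05, below all 10000 random lists, and with lines at -4.63 in A129-2, -2.96 in AOS-14 and -2.70 in AOS-16. At least 1 TPM was reached in all 3 AG-haESC lines by 12 of the 16, and 0 of them stood in another list. Acta2, smooth muscle actin, was at 7.45 ± 4.68 TPM against 585 and 588 and Thbs1, a matrix glycoprotein, at 5.68 ± 2.22 against 429 and 430.3. S100a4, a calcium-binding protein of fibroblasts and macrophages, was at 2.05 ± 2.10 TPM against 276 and 298 and with Egr1 and Acta2 was among the 5 genes with the lowest differences, the others being Eef1a1 and Rn45s, for which no fold is given. Y-linked transcripts, which an XX genome does not encode, were present in both ESC XX libraries, with Eif2s3y at 3.16 and 2.63 TPM, and the 2 measured by the filter were lower in AG-haESCs (Eif2s3y -1.74, Ddx3y -1.21). The macrophage gene Lyz2 was at 14.7 and 10.6 TPM in ESC XX and listed at 0 in the 3 lines. Of 6 haematopoietic genes 3 were lower in AG-haESCs (median -0.83 ± 0.20), and the list's percentile went from 1.14 to 4.82 without A129-2, 6.37 without the second ESC XX library and 27.5 with FPKM as deposited.

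Imprinted genes differed in both directions, beside the fibroblast genes (median -3.28) and the Y-linked Eif2s3y (-1.74) that were higher in the same ESC XX libraries. Of 16 maternally expressed genes 5 were lower in AG-haESCs and none higher (median -0.80 ± 0.33, below the central 95% of random lists), among them Osbpl5 (-2.74 ± 0.26) and H19 (-1.86 ± 1.34), and Igf2r was not called (-0.39 ± 0.24). Rian met the bound as well (-1.75 ± 1.57), but only through the AOS lines, since A129-2 at 111 TPM lay next to the ESC XX libraries at 112 and 118. Of 23 paternally expressed genes 4 were higher and 5 lower (median 0.17 ± 0.48, percentile 86.3). The list's median was -0.13 without A129-2 (percentile 21.9) and 0.32 without AOS-14 (98.2), and its percentile was 98.5 with quantile normalization and 97.7 with FPKM as deposited. Examples were Igf2 at 5.22 ± 3.08 TPM against 138 and 135 (-4.50 ± 0.82) and Peg12 at 17.5 ± 12.7 against 1.84 and 3.09 (2.33 ± 0.97). Of 14 glycolysis genes 3 were higher (median 0.39 ± 0.60), with line medians of 0.36 in A129-2, -0.17 in AOS-14 and 1.03 in AOS-16 and with Slc2a1 at 1658 TPM in AOS-16 against 629 in A129-2. These line medians keep any offset of the library. The list lay above the central 95% of random lists, but at percentile 85.8 without AOS-16. Of 10 trophoblast genes 3 were higher and 1 lower (median 0.54 ± 0.40), with the transcription factors Gata3 and Hand1 higher by 1.69 ± 0.23 and 1.52 ± 0.43. Its percentile among random lists was 99.2, and 86.2 without AOS-14. The counts of higher and lower genes were 0 and 3 of 16 for cholesterol and fatty acid synthesis, where Fasn, the fatty acid synthase, differed by -2.16 ± 0.30. They were 0 and 2 of 13 for p53 targets, whose percentile was 2.00 and 34.0 without AOS-14, 3 and 2 of 12 for post-implantation epiblast, 1 and 4 of 11 for primitive endoderm, 2 and 1 of 8 for mesoderm and neural, and 1 and 1 of 5 for Sertoli. They were 0 and 0 for Leydig (of 3), spermatid (of 7) and housekeeping genes (of 10). With a filter of at least 5 the primitive endoderm median went from -0.23 (percentile 17.8) to -1.21, below the central 95% of random lists. Without AOS-16 the cholesterol and spermatogonial lists also lay below it (percentiles 1.51 and 2.41).

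In all, 1936 of 14251 genes met the rule, 806 higher and 1130 lower in AG-haESCs. In the simulated data, whose shares do not carry over, the rule called 714 of 12393 unchanged genes. Of the genes kept, 49.5% had no overlap between the groups. Chance gives 20% for 3 independent libraries against 2 and 50% for 3 against 1. The ESC XX libraries differed by little more than counting noise, so the 50% is the nearer reference. Averaged to 1 library they gave 54.3%. With 1 library against 2, the same rule called 1745 genes in A129-2, 1006 in AOS-14 and 892 in AOS-16 against the other lines, and 2050 to 2424 genes in the mean of the ESC XX libraries against each pair of lines. Without A129-2 the count between the groups was 2404. Strain, medium, the sort named and feeder treatment differed together with the groups and cannot be told apart from ploidy or parental origin. No test was run across the separately normalized tables, so these differences are described by size and overlap alone.

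**Figure D3:**
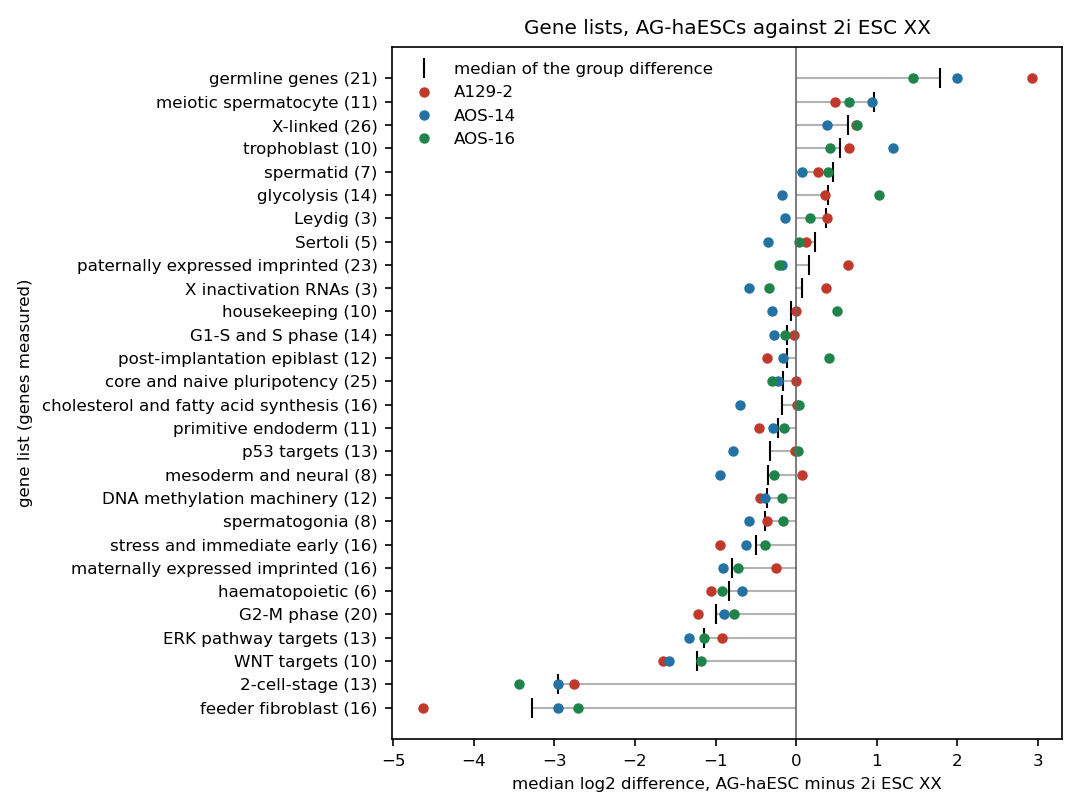
Median log2 difference between AG-haESCs and ESC XX for 28 gene lists with at least 3 measured genes (number measured in brackets); bars mark the median of the group difference and circles each line's median difference to the mean of the 2 ESC XX libraries. The same group median over all genes was removed from each line, so circles keep any offset of a line's library. The feeder fibroblast and 2-cell-stage lists lie lowest, at -3.28 and -2.95, and the germline list highest, at 1.79.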

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

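The alternatives that left out short genes, X-chromosomal genes or genes listed at 0, or averaged the ESC XX libraries, were chosen after seeing the data, and the rest before. The number of genes called between AG-haESCs and round sperm stayed between 7049 and 10496 under all alternatives run, and leaving out each line gave 7780 to 9409. Against ESC XX the count was 1936, and 477 at a log2 difference of at least 2, which by construction keeps fewer genes. Leaving out each library gave 1988 to 2404, the highest without A129-2, and the other alternatives gave 1484 to 2796, with 1711 when X-chromosomal genes were left out. With an estimated correlation 0 of 29 lists passed camera against round sperm. A higher correlation is argued against as the cause for the X-linked, Y-linked, paternally expressed and housekeeping lists. Their estimates (-0.0174, -0.0709, -0.0384 and -0.00227) lay under the preset 0.01. For the other lists the part of correlation was not tested apart from the 2 residual degrees of freedom on which this setting rests. The lack of calls in this setting thus cannot be put down to correlated genes. Fry, which asks only whether a list changed where most genes tested were called, called 14 of 15 lists, all but the fibroblast list. These 15 of the 29 lists had passed camera at the preset correlation. Without each line 16 to 17 passed. Of 28 lists 15 lay outside the central 95% of random lists against ESC XX, and 13 to 16 did without each library. The agreement among AG-haESC lines, as mean Pearson's r, was 0.892. It was 0.953 with no filter on low values, which adds genes at 0 in all lines, 0.842 with a pseudocount of 0.1 and 0.944 with short genes left out at the same total. The cause was not tested for the pseudocount, and leaving out short genes was not run apart from the rescaling. None of the 120 genes named for round sperm or the 124 for ESC XX that were called changed sign under any alternative. Without a line, 28 of the 99 called genes named for round sperm lost their call, and 14 of 86 did so under some alternative against ESC XX, apart from the threshold of 2. Depth of about 8.38 M fragments in A129-2 limits what can be said of genes near 1 FPKM. No paired analysis was possible because the groups share no replicate pairing and round sperm has 1 library.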

Other observations

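The tests and genes in this part were all chosen after the results they bear on were seen. Members of multi-copy gene families of the X chromosome were higher in AG-haESCs than in ESC XX: 14 of 17 Rhox genes met the bound (median 2.44), as did 8 of 9 Xlr genes (median 3.86) and all 7 measured Magea genes (median 3.10), and none of the 3 families had a lower member. These medians exceed the 0.95 of the 314 X-chromosomal genes with a mean of at least 10 TPM. The families were taken at the lower filter of at least 1 TPM in at least 1 library, so the 2 sets are unlike. At that lower filter 233 of 567 X-chromosomal genes were called higher. Copies within each family share reads. AG-haESC lines also differed in maternally expressed RNAs of the Dlk1 domain: Mirg was at 7.08 FPKM in A129-2, 1.24 in AOS-14 and 1.33 in AOS-16 against 8.35 and 7.34 in ESC XX, and like Meg3 and Rian it was higher in A129-2 than in both AOS lines. Of the paternally expressed genes there, Dlk1 (1.04, 1.04 and 1.26 FPKM, lines in the same sequence) and Dio3 (0.644, 0.940 and 0.276) were not highest in A129-2, whereas Rtl1 (0.583, 0.0903 and 0.0370) was.

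X-chromosomal genes stood near a 2-fold difference between AG-haESCs and ESC XX. No feeder profile was measured, so feeder cells were assumed to have 1 active X per 2 autosome sets and the ESC XX cells 2. Feeder RNA in ESC XX would then have to make up 96.5% of those libraries to give this shift. That would lower the pluripotency list in ESC XX by 4.86 on the log2 scale, but the list differed by -0.16 (95% bootstrap interval -0.60 to 0.04). Under that assumption this argues against feeder RNA as the source of the shift. XY cells under an XX label are argued against by the Y-linked genes, none of which exceeded 1.63% of its X partner in an ESC XX library. The median of 0.95 prompted the hypothesis of 1 active X per 2 autosome sets in the ESC XX cells and so cannot test it, but each of 4 equal parts of the chromosome in gene order showed the shift, with medians from 0.78 to 1.13, as that hypothesis needs. Whether an X was lost or inactivated stays open: 4 genes known to escape inactivation differed by a median of 0.73 but ranged from 0.20 (Ddx3x) to 0.93 (Kdm6a). Xist, the RNA that coats an inactive X, was at 5.86 and 6.03 FPKM in ESC XX against 0.855 to 1.28 in the AG-haESC lines. Whether the ESC XX cells or feeder cells among them gave this Xist was not tested.

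Chromosome 8 set A129-2 apart from the AOS lines. Random lists matched on mean expression did not show the shift, with the chromosome's median at percentile 100 of 10000, which argues against expression level alone as the cause. The chromosome was picked for this shift, so the percentile says nothing about chance. An extra copy in A129-2 may account for it as a hypothesis, since each of 4 equal parts of the chromosome in gene order showed the shift, from 0.89 to 1.00 relative to the other autosomes, where a doubling gives 1. Both AOS lines also lay below ESC XX on this chromosome, at -0.28 and -0.21, outside their other autosomes (-0.09 to 0.05 and -0.07 to 0.08), as a gain in part of the ESC XX cells would give. No DNA was measured in the files used here, so copy number itself was not tested.

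Fibroblast genes were higher in ESC XX. RNA of male feeder cells is a candidate source: the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 2.51 FPKM in ESC XX (mean of 2) against at most 0.128 in an AG-haESC library, and each of the 4 was higher in both ESC XX libraries than in all 3 lines, although a step to remove feeders is named for ESC XX. In ESC XX these 4 genes stood at only 0.562% to 1.63% of their X partners. Whether so little male RNA could give the fibroblast values was not tested. The protocol of the AG-haESCs names a sort for haploid cells, a gate that would remove diploid feeders, and whether the AOS libraries hold some of the same RNA was not settled. Acta2, Tagln and Thbs1 were at a median of 62.5 times their AOS level and 5 collagen genes at 9.13 times, a 6.85-fold gap, but these 3 are the members of the list with the largest differences, so the gap excludes nothing. An effect of serum on either cell type also stays open, as the media differed with the groups.

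Genes under 200 nt took 12.7% of the FPKM total in AOS-14 and 6.26% in round sperm, with 151 and 68 of 1166 such genes above 0, against at most 8 in any other library, including an ESC XX library of near equal depth (17.3 M against 17.8 M fragments).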
